A study of Oryctolagus cuniculus with 3 samples.

How the data were processed

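RNA was measured by sequencing in 3 libraries of RCE1(5T5), a cell line from rabbit corneal epithelium, with 1 library for each of 3 stages: non-differentiated cells on day 4, committed cells on day 6 and terminally differentiated cells on day 10. Per the labels' protocols, the cells grew together with mitomycin C-treated 3T3 cells (a mouse fibroblast line used as a feeder layer), the feeder cells were taken off with EDTA before extraction, total RNA was prepared with Trizol, and libraries were made with an Illumina TruSeq RNA kit. With 1 library per stage there is no replicate check of any difference. No test was run and no p-value is given, because genes are not replicates. Stage, day and library cannot be separated in this design.

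Each deposited table lists 38696 coding sequences under 20536 gene names. Per the file headers, the authors gave fragment counts and read counts. The deposited values of both are expected counts, made before deposit; many are fractional, which is how counts look when shared reads are split among coding sequences. Per the file headers, the tables also give a raw transcript count, a coverage signal that equals reads times an implied read length of 75 divided by the coding length. The authors' FPKM, RPKM and TPM columns are normalized for length and depth, and the deposited TPM values sum to between 999978.8 and 999985.6 per library. The genome build was OryCun2.0, per the submitters' processing notes. The aligner, the counting program and whether counting used strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart from these counts.

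The deposited fragment counts were summed over the coding sequences of each gene name and rounded to whole numbers. Before rounding, the total was 10171693 fragments on day 4, 12582706 on day 6 and 10899578 on day 10. The rounded totals used for scaling were 10171633, 12582648 and 10899544. Counts scaled to library size (CPM, counts per 1e6) were computed with trimmed mean of M values (TMM) factors of 1.071, 0.958 and 0.974 from edgeR 4.0.16 in R 4.3.3. The design assumed whole counts; as the tables hold estimated counts, these were rounded first and treated in the same way. A gene was measured when it reached 1 CPM in at least 1 library, which held for 12818 genes. A difference is the difference of log2(CPM + 1), which understates the change of low genes. A gene is said to have risen or fallen when that difference was at least 2-fold. Folds printed for single genes are ratios of CPM without the added 1, with the exact 95% Clopper-Pearson interval of the fragments of the pair of libraries compared. PCR copies are not independent molecules and cultures vary, so these intervals cover counting error only. Where a library had no fragment of a gene, the fold is a lower bound computed against 3 fragments, which is 0.275 CPM on day 4, 0.249 CPM on day 6 and 0.283 CPM on day 10.

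Before the data were examined, 49 gene lists were fixed, 6 of them as main lists: corneal epithelial differentiation, basal and limbal progenitor, S phase, G2 and M phase, cornified envelope and stratification, and fibroblast and feeder markers. For each list, the median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Members of the list itself were not left out of the draws. A list is said to stand above or below random lists when its percentile was over 97.5 or under 2.5. This describes these libraries and is not a test of the conditions. Over 147 list comparisons, about 7.3 would stand apart if the members of each list were unrelated genes, and 67 did. Lists share genes and the comparisons share libraries, so the 147 are not separate results. Genes of a list can also move together for any reason that differs between single libraries. The median and the mean of a list differed in sign in 11 of them. In 13 list comparisons at least 1 member had no fragment in 1 of the libraries, and setting those members at their bound changed 0 of the medians. The bound keeps the direction of such a member, so a median could hardly move.

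The rule for naming genes was also fixed before the data were examined. It takes 27 key genes; the 8 named genes with the largest rise and the 8 with the largest fall in each comparison among those with at least 10 CPM in the higher library; up to 2 members of each list with the largest rise and up to 2 with the largest fall, where at least 2-fold; and the 5 most abundant genes of each library. Of the key genes, 23 were measured under their symbol; the other 4, KRT14, ABCG2, ALDH3A1 and NOTCH1, were not analysed here. Further members of a list and the genes without a name that the text singles out were chosen after their values were seen.

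Gene names are those in the tables. Of 5185 genes with a LOC name, 718 had a symbol in the RefSeq gene table of assembly mOryCun1.1 and 671 took it. That table was used for names and neighbours only, because its build differs from that of the counts. A set of 15 gene names had been turned into dates, as a spreadsheet does, and stayed as they were. Among 1879 genes with at least 1000 fragments on average, 58 had counts within 1% of those of another gene in all 3 libraries, as reads split evenly between near-identical copies would give. Whether reads of other genes with close relatives, such as ACTA2, GAPDH, EEF1A1, LDHA, RLN1 and ribosomal protein genes, were shared with those relatives was not tested.

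The calling of changed genes was checked on simulated counts drawn from the mean CPM of the real genes and the real library sizes, with 200 genes changed. The simulated counts carried counting error only. The summing of coding sequences, the naming and the TMM scaling were not run on them. The changed genes were taken from those with a mean of at least 10 CPM, so the recovery of lower genes was not tested. For day 6 against day 4, among 12506 measured genes, 50 of 50 genes changed 3-fold were called and 0 of 50 changed 1.5-fold, and 1 of 12306 unchanged genes was called. With counting error alone at these levels, a 2-fold threshold was bound to give about that result. Random lists drawn on the real differences stood apart in 5.2% of 600 comparisons. With a shift of 1 added to the log2 differences of 25 genes, 60 of 60 list comparisons were found, which so large a shift made all but certain. The alternatives planned before the data were examined were DESeq2 1.42.0 size factors, CPM with no TMM, a pseudocount of 0.1 or 5, a minimum of 5 CPM, no minimum, the highest coding sequence of each gene in place of the sum, a 4-fold threshold, and random lists with no matching. The alternatives added after seeing the data were the deposited TPM, read counts in place of fragments, and leaving out LOC genes. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.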

Results

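The transcriptome of RCE1(5T5) rabbit corneal epithelial cells was read at 3 stages of their differentiation in culture, to describe how expression changes as proliferating cells commit and then differentiate. There was 1 library for each stage. The libraries held 10171693 fragments (non-differentiated, day 4), 12582706 (committed, day 6) and 10899578 (terminally differentiated, day 10), and fragments were counted for 14527, 14782 and 14994 genes. No difference below has a replicate check, and brackets give 95% counting intervals only. KRT5, a keratin of basal epithelial cells, was the most abundant gene on days 4 and 6, with 15650 and 23374 CPM. It was second on day 10 with 13552 CPM, behind the elongation factor EEF1A1 at 16074 CPM. The KRT5 values and ranks are those of 2 coding sequences summed. These were at 10879.6 and 4770 CPM on day 4, and at 18013.6 and 5360.8 CPM on day 6. The other genes among the 5 most abundant of a library were ANXA1, LDHA, GAPDH, the mitochondrial COX1 and LOC100344686. The last has no symbol in the tables and lies next to KRT19 in the mOryCun1.1 assembly. Ribosomal protein genes took 7.52% of the scaled counts on day 4, 11.15% on day 6 and 12.1% on day 10, while mitochondrially encoded genes took 2.37%, 2.08% and 2.09%.

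The first comparison asks what changed at commitment, between day 4 and day 6. Genes of corneal differentiation rose: 9 of 17 measured members of that list rose and 0 fell. KRT3, the type II keratin of the corneal pair, went from 149.6 to 954 CPM, a rise of 6.38-fold [6.05 to 6.72]. Its partner KRT12 had 0 fragments on day 4 and 19.3 CPM on day 6, at least 70.2-fold higher. KRT13 rose 10.9-fold [8.78 to 13.7], and the median of the list was 1.04 on the log2 scale, at percentile 100. PAX6, a master regulator of eye development, rose 3.01-fold [2.71 to 3.35]. The epithelial regulator TP63, which is also in the basal and limbal progenitor list, rose 2.9-fold [2.64 to 3.18]. The epithelial transcription factors EHF and ELF3 rose 3.86-fold [3.34 to 4.46] and 2.87-fold [2.48 to 3.32]; their list as a whole did not stand apart (percentile 2.63), although 6 of the 11 alternatives placed it below random lists.

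Among cornified envelope and stratification genes, 13 of 35 rose and 3 fell between day 4 and day 6 (median 0.48, percentile 99.96). The antimicrobial S100A9 rose from 0.826 to 286 CPM, 346-fold [182 to 758], and S100A8 from 2 fragments to 595. KRTDAP, a protein of differentiating keratinocytes, rose 103-fold [40 to 381]. The crosslinking enzyme TGM1 rose 3.59-fold [2.85 to 4.55]. SERPINB2, a protease inhibitor, went the other way and fell 36.1-fold [28.2 to 46.9]. Basal and limbal progenitor genes did not stand apart: 3 of 20 rose and 1 fell (median 0.08, percentile 59.2). KRT15 rose 6.92-fold [5.88 to 8.2] and TXNIP 6.3-fold [5.57 to 7.15], while ID3 fell from 45.7 to 19.6 CPM. TP63, whose rise is given above, was the other riser of this list. ITGA6 and ITGB4, the hemidesmosomal integrin chains, were at 590 and 447 CPM on day 4 and 420 and 509 CPM on day 6.

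Interferon response genes rose more uniformly than those of any other list shown here at this step: 25 of 27 rose and 0 fell, with a median of 2.51 at percentile 100. IFI44L rose 35.2-fold [19 to 74.1], RSAD2 25.8-fold [16.2 to 43.9] and IRF7 8.21-fold [6.86 to 9.89]. The chemokine CXCL10, which interferon induces, went from 0.459 to 18.7 CPM. In the list of cytokines and innate defence 8 of 24 genes rose and 3 fell (median 0.37, percentile 98.6), a call lost with a pseudocount of 0.1 (percentile 95.64). Of the antigen presentation list, 3 of 9 rose, among them B2M at 2.27-fold [2.06 to 2.52]; its percentile of 99.8 fell to 94.07 with no minimum on CPM and to 89 with the highest coding sequence of each gene. The immune cell list did not stand apart (1 of 6 up, percentile 93.9). Its riser was CD68, a gene of macrophages and of lysosomes, which went from 61 to 302 fragments by day 6 and 722 by day 10, while the myeloid genes TYROBP and FCER1G had 0 fragments in all 3 libraries.

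The glycolysis and hypoxia response lists also stood above random lists between day 4 and day 6. Of 24 measured glycolysis genes 11 rose and 0 fell (median 0.92, percentile 100), with GPI at 3.27-fold [3.16 to 3.38] and the lactate exporter SLC16A3 at 6.5-fold [5.33 to 7.99]. LDHA rose 3.37-fold [3.33 to 3.41] and its sister LDHB was 1.74-fold higher [1.71 to 1.78]. Of 24 hypoxia genes 12 rose and 0 fell (median 1.06, percentile 100), led by the oxygen sensor EGLN3 at 11.4-fold [9.28 to 14.2] and the mitophagy receptor BNIP3 at 6.42-fold [5.86 to 7.06]. TKT, an abundant enzyme of the corneal epithelium, rose 2.5-fold [2.45 to 2.56], and ALDH1A1 2.06-fold [1.96 to 2.17].

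Genes that build ribosomes and genes that code for ribosomal proteins moved apart. Of 33 ribosome biogenesis genes 23 fell and 0 rose by day 6 (median -1.29, percentile 0). RRS1 fell 4.78-fold [3.9 to 5.89] and HEATR1 4.29-fold [3.84 to 4.79]. Of 65 ribosomal protein genes 6 rose and 0 fell, with a median of 0.75 at percentile 100; RPS21 rose 2.9-fold [2.79 to 3.01]. Across genes, the difference between day 6 and day 4 went with coding length at a Spearman rho of -0.127, so that short genes lay slightly higher; genes are not independent replicates. It was 0.077 for day 10 against day 6 and -0.032 for day 10 against day 4. S phase genes stood below random lists, with 4 of 34 down and 0 up (median -0.34, percentile 0.68), while G2 and M phase genes did not stand apart, with 1 of 41 down (median -0.2, percentile 10.2). CDC6, which loads the replicative helicase, fell 2.77-fold [2.29 to 3.37]. The proliferation marker MKI67 was at 342 CPM on day 4 and 304 CPM on day 6, and MYC at 90.2 and 47.3 CPM.

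The lists of the EGF receptor and its ligands, of the basement membrane and of fibroblast markers stood below random lists at this step. Of 21 genes of the EGF receptor list 8 fell and 1 rose (median -0.52, percentile 0.15): FOSL1, a target of that pathway, fell 20.2-fold [15 to 27.8] and the ligands EREG and AREG fell 10.2-fold [6.72 to 16.1] and 6.27-fold [5.28 to 7.48], whereas the receptor EGFR was at 203 and 181 CPM. Of 25 fibroblast and feeder markers 7 fell and 0 rose (median -0.86, percentile 0), with THBS1, a matrix glycoprotein, down 11.5-fold [10.4 to 12.7] and TAGLN down 5.44-fold [4.47 to 6.67]. The fibrillar collagen gene COL1A1 was at 542 CPM on day 4 and 312.5 CPM on day 6. Of 12 genes of epithelial to mesenchymal transition 6 fell and 0 rose (percentile 0), of 24 basement membrane genes 7 fell and 0 rose (percentile 0.24), with NID1 down 5.89-fold [5.01 to 6.96], and of 6 keratocyte markers 4 fell and 1 rose (percentile 0.02), with OGN and ASPN among the falls at 41 fragments or fewer. Lists share genes. Also in another list are 5 of the 12 transition genes, 4 of the 24 basement membrane genes and 3 of the 6 keratocyte markers. DCN, a keratocyte marker that fell, is also a fibroblast marker. Those lists moved together with the fibroblast markers at this step, but they are not fully separate from them. The basement membrane list turned after it and stood above random lists from day 6 to day 10 (4 of 24 up, 1 down, percentile 99.9). The largest falls among named genes also included IL20, CYR61, CYP1B1, ADAMTS15 and GPRC5A, each by 12-fold or more. Heat shock genes stood below random lists, with 4 of 16 down and a percentile of 0.02.

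In all, 1033 of 12818 measured genes rose and 863 fell between day 4 and day 6. In a simulation with no effect, counting error alone gave 0 and 0 among its 12511 measured genes. With the deposited TPM the counts were 558 and 1629, with a pseudocount of 5 they were 472 and 451, and at a 4-fold threshold 151 and 86. The share of risers among the changed genes was 54.5%, against 39.3% with no TMM and 25.5% with TPM, where the median of all genes moved to -0.14 and -0.30 on the log2 scale.

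**Figure D1:**
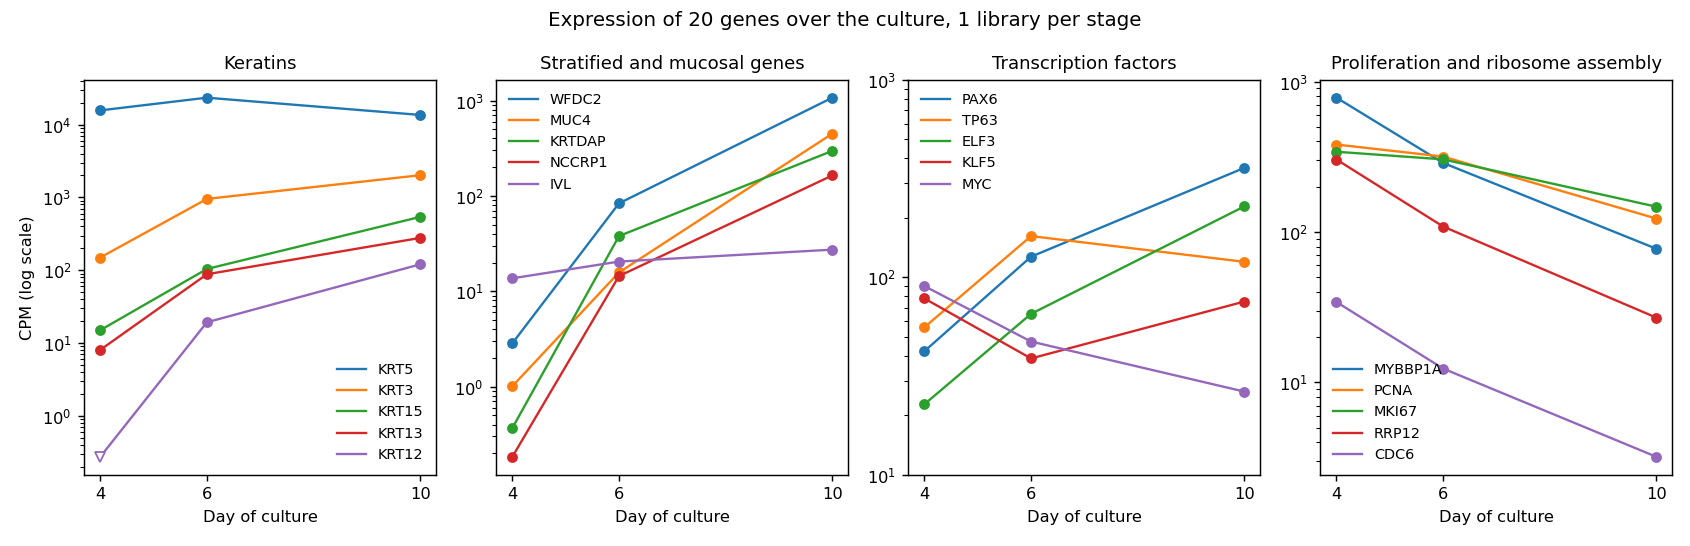
CPM on a log axis (vertical) of 20 genes against the day of culture (horizontal), in 4 groups. Each point is 1 library per stage with no error bar, and the open triangle marks KRT12 on day 4, which had 0 fragments and is drawn at the floor of 0.275 CPM. KRT3 climbs from 149.6 to 2018 CPM, while RRP12 and CDC6 fall at each step.

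The second comparison asks what changed between commitment and terminal differentiation, from day 6 to day 10. The corneal differentiation list stood above random lists again: 8 of 17 rose and 0 fell (median 0.97, percentile 100). KRT12 rose 6.24-fold [5.43 to 7.21] and KRT3 2.12-fold [2.07 to 2.16]. AQP5, a water channel, rose 28.4-fold [21.9 to 37.5] and PSCA, a surface protein, 8.16-fold [7.15 to 9.33]. PAX6 rose 2.82-fold [2.65 to 2.99] and ALDH1A1 2.13-fold [2.06 to 2.21], while TKT was at 2514 CPM on day 6 and 1500 CPM on day 10. Of 35 cornified envelope and stratification genes 16 rose and 3 fell (median 0.68, percentile 100). CDSN, an adhesion protein of cornified cells, rose 33.4-fold [20 to 60.2] and the protease KLK6 33-fold [19.4 to 60.9]. TGM1 fell 4.17-fold [3.25 to 5.39] and S100A9 fell 3.36-fold [3.12 to 3.62]. The envelope precursor IVL was at 20.5 CPM on day 6 and 27.3 CPM on day 10.

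The mucin list rose further at this step. MUC4, a membrane mucin, rose 28.5-fold [24.7 to 33.2] to 450 CPM, and 5 of the 9 genes of the mucin list rose (percentile 99.98, from day 4 to day 6 also 5 of 9, where a pseudocount of 5 gave a percentile of 95.35). The largest rises of named genes also included RARRES1, WNT11, FCGBP, SPINK7, AIF1L, CYP4B1 and RLN1, the last from 75.2 to 3696 CPM. Of 17 retinoid genes 7 rose and 2 fell (percentile 100); CYP26A1, which breaks down retinoic acid, had 0 fragments on day 6 and 6.59 CPM on day 10, at least 26.5-fold higher. Tight and adherens junction genes stood above random lists, with 7 of 24 up and 1 down (percentile 99.98); NECTIN4 rose 3.01-fold [2.73 to 3.33] and CGN 2.13-fold [1.81 to 2.5]. Gap junction genes stood below (2 of 8 down, percentile 1.44), with GJB2 down 2.42-fold [2.25 to 2.6], a call lost with TPM (percentile 4.19). Basal and limbal progenitor genes stood above random lists (percentile 99.6), with only 3 of 20 up and 2 down: KRT15 rose 5.19-fold [4.88 to 5.52], TXNIP rose 2.35-fold [2.23 to 2.48], KRT17 fell 3-fold [2.69 to 3.36] and the cadherin CDH3 fell 2.69-fold [2.46 to 2.95].

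Both cell cycle lists stood below random lists after day 6. Of 34 S phase genes 25 fell and 0 rose (median -1.29, percentile 0), with GINS2 down 4.67-fold [3.44 to 6.45] and the sliding clamp PCNA down 2.58-fold [2.42 to 2.75]. Of 41 G2 and M phase genes 13 fell and 0 rose (median -0.64, percentile 0); AURKB fell 4.35-fold [3.63 to 5.24] and MKI67 2.06-fold [1.94 to 2.19]. CDKN1A, an inhibitor of the cell cycle, rose 2.18-fold [2.02 to 2.37], and the list of inhibitors and p53 targets stood above random lists with 4 of 27 up and 1 down (percentile 99.4). Of the ribosome biogenesis genes 16 of 33 fell and 0 rose (median -1, percentile 0), with RRP12 down 4.04-fold [3.55 to 4.6]. Ribosomal protein genes shifted little: 0 of 65 rose or fell, with a median of 0.11 at percentile 98.4, which dropped to 86.8 without matching on expression, 97.44 with a minimum of 5 CPM and 89.4 with matching on coding length too.

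The sterol synthesis list stood below random lists in this interval, with 9 of 22 down and 1 up (median -0.89, percentile 0). FDPS, which makes farnesyl diphosphate, fell 5.96-fold [5.44 to 6.55], while HSD17B7 rose 2.3-fold [2.15 to 2.45]. The amino acid transporter SLC7A5, the folate enzyme MTHFD2, the lectin LGALS1 and LRRC59 each fell by more than 5-fold, and DLK1, THBS2 and THBS1 fell 11.8-fold [8.76 to 16.3], 10.5-fold [7.99 to 14.1] and 6.81-fold [5.14 to 9.16]. Of the fibroblast and feeder markers 8 fell and 1 rose (median -0.81, percentile 0), with COL6A2 down 4.06-fold [3.64 to 4.53] and THY1 up 4.59-fold [3.93 to 5.38]. Interferon response genes did not stand apart (2 up, 5 down, percentile 16.8): IRF7 rose 4.77-fold [4.48 to 5.08] and RSAD2 fell 4.97-fold [3.97 to 6.29]. Glycolysis genes did not either, with 1 of 24 up (percentile 78.1). Hypoxia genes stood above random lists, with 4 up and 3 down (percentile 99.9).

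Between day 6 and day 10, 1058 genes rose and 910 fell, against 1 and 0 by counting error alone in the simulation. With a pseudocount of 5 the counts were 562 and 452, and at a 4-fold threshold 215 and 32.

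**Figure D2:**
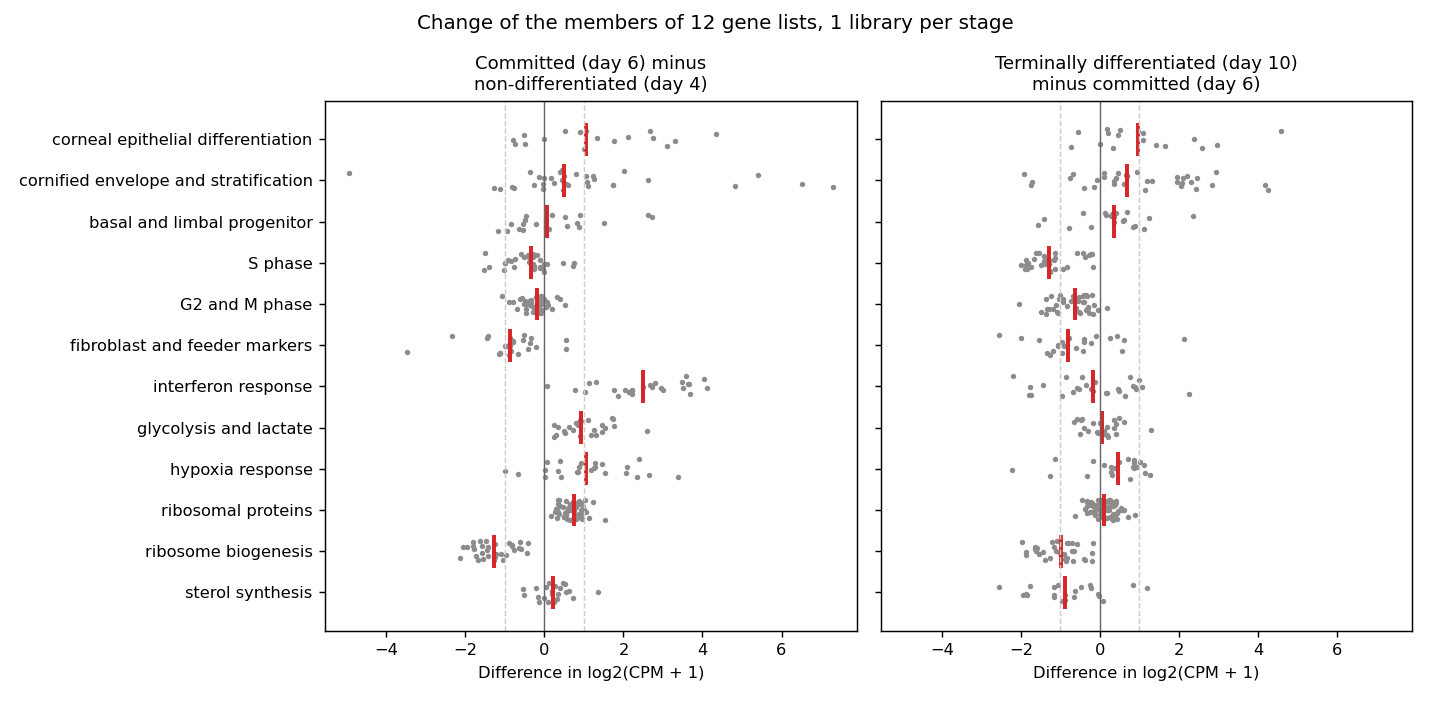
Difference in log2(CPM + 1) (horizontal) of each measured member (grey points) and the median (red bar) of 12 gene lists (vertical), for day 6 minus day 4 (left) and day 10 minus day 6 (right). Dashed lines mark 2-fold. The interferon median is 2.51 in the left panel and -0.17 in the right, and the S phase median goes from -0.34 to -1.29.

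The third comparison sets terminally differentiated against non-differentiated cells. Over the whole interval 10 of 17 corneal differentiation genes rose and 0 fell (median 1.33, percentile 100). KRT3 rose 13.5-fold [12.8 to 14.2], KRT13 34.4-fold [27.9 to 43.1], PAX6 8.48-fold [7.7 to 9.36] and ALDH1A1 4.39-fold [4.19 to 4.61], and KRT12 was at least 438-fold higher. Of the cornified envelope and stratification genes 24 of 35 rose and 3 fell (median 1.75, percentile 100); KRTDAP rose 808-fold, from 4 fragments to 3150. WFDC2, a secreted protease inhibitor, rose 377-fold [265 to 555] to 1071 CPM, MUC4 445-fold [249 to 893], and NCCRP1, FCGBP and AQP5 rose from fewer than 5 fragments to 163.9, 147.1 and 139 CPM. SPINK9, at 0 fragments on day 4, was at least 240-fold higher. Basal and limbal progenitor genes did not stand apart (6 of 20 up, 1 down, median 0.04, percentile 58.7); KRT15 rose 35.9-fold [30.7 to 42.2] and KRT17 fell 4.67-fold [4.21 to 5.2], with KRT5 at 0.866 of its day 4 level. That value sums 2 coding sequences filed under KRT5, at 0.927 and 0.727 of their day 4 levels. Other key genes that neither rose nor fell were ITGA6, ITGB4, EGFR, KLF4, KLF5, TGM1, MUC1, IVL, TKT and CDKN1A; IVL and MUC1 came closest, with log2 differences of 0.95 and 0.93.

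Of 34 S phase genes 26 fell and 0 rose (median -1.77, percentile 0), and of 41 G2 and M phase genes 18 fell and 0 rose (median -0.78, percentile 0.01). PCNA fell 3.1-fold [2.92 to 3.31], MKI67 2.32-fold [2.19 to 2.46] and MYC 3.42-fold [2.99 to 3.92]. All 33 ribosome biogenesis genes fell (median -2.25, percentile 0), RRS1 by 18.2-fold [12.4 to 27.9] and MYBBP1A by 10.1-fold [9.41 to 10.9]. Of 65 ribosomal protein genes 16 rose and 0 fell (median 0.86, percentile 100), where random lists matched on coding length had a median of 0.60. Those random lists could include ribosomal protein genes. Interferon response genes stayed above day 4, with 22 of 27 up and 0 down (median 2.36, percentile 100). So did glycolysis genes (15 of 24 up, 0 down, percentile 100) and hypoxia genes (16 of 24 up, 2 down, percentile 100), with LDHA at 2.71-fold [2.68 to 2.74] and LDHB at 2.65-fold [2.6 to 2.7]. Autophagy and lysosome genes rose in 14 of 30 cases with 0 down (percentile 100), among them the cathepsins CTSS at 29.9-fold [13.5 to 82.7] and CTSH at 14.1-fold [10.8 to 18.7]. Of 13 Notch pathway genes 6 rose and 1 fell (percentile 99.6), including the ligand DLL1 at 5.13-fold [4.28 to 6.19]; with no minimum on CPM the percentile was 95.35.

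Of 25 fibroblast and feeder markers 20 fell and 2 rose from day 4 to day 10 (median -1.61, percentile 0). THBS1 fell 78.4-fold [60.3 to 104] and COL6A2 7.41-fold [6.67 to 8.23], while THY1 rose 3.92-fold [3.37 to 4.58] and TIMP1 2.18-fold [1.88 to 2.55]. The other large falls, in the axon guidance factor SLIT2, the chromatin protein HMGA2, DLK1, THBS2, LTBP2 and IL20, were each over 25-fold. The neural cadherin CDH2 fell from 167 fragments to 2. Those genes were named for their falls, so the direction they share with the fibroblast markers follows from that choice. Of the 12 genes of epithelial to mesenchymal transition 9 fell and 0 rose (percentile 0), with PRRX1 down 11.1-fold [8.44 to 14.8].

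From day 4 to day 10, 2190 genes rose and 2024 fell, against 1 and 1 by counting error alone. With TPM the risers numbered 1383; with a pseudocount of 5 the counts were 1324 and 1319, and at a 4-fold threshold 603 and 396. The share of risers was 52%, against 31.9% with TPM, where the median of all genes moved to -0.31.

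Taking both steps in order, 211 genes rose at each step and 142 fell at each, against 85.3 and 61.3 for independent steps; 48 rose then fell and 62 fell then rose, against 73.3 and 71.2. Rises at a single step numbered 774 to day 6 and 785 after it, falls 659 and 720, and 9417 genes changed at neither. Both steps share the day 6 library, whose counting error alone would add genes that turn, and the simulation with no effect gave 0 in each class with changes at both steps. With a pseudocount of 0.1 the 4 classes held 400, 269, 131 and 179 genes against 169.9, 121.5, 157.5 and 131.1 for independent steps, and with 5 they held 89, 53, 24 and 25 against 20.7, 15.9, 16.6 and 19.8. Genes that kept their direction thus outnumbered independent steps under each of these settings, while the classes that turned lay below or above them depending on the pseudocount. The class that fell then rose also depended on the minimum: with none on CPM, its 62 genes stood above the 57 for independent steps. KRT3, KRT12, KRT13, KRT15, PAX6 and MUC4 rose at both steps, and RRP12, MYBBP1A, THBS1 and DLK1 fell at both.

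**Figure D3:**
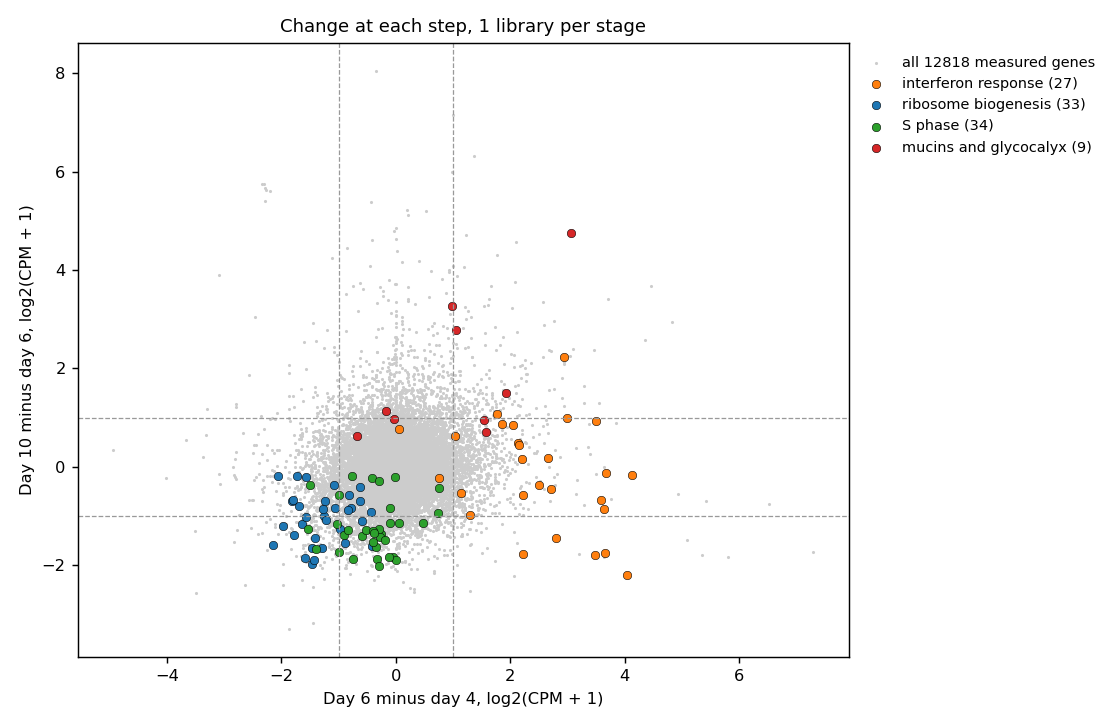
Difference in log2(CPM + 1) at the first step (day 6 minus day 4, horizontal) and at the second (day 10 minus day 6, vertical) for the 12818 measured genes in grey, with 4 gene lists in colour and dashed lines at 2-fold. The 33 ribosome biogenesis genes lie to the lower left, and 25 of the 27 interferon response genes lie right of the 2-fold line.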

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

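No paired analysis was possible because each stage has 1 library. The deposited TPM, read counts and leaving out LOC genes were chosen after seeing the data. Across 11 alternatives each, the 18 comparisons of the 6 main lists kept their place relative to random lists (198 of 198 checks). Their medians changed sign in 4 checks, all of the basal and limbal progenitor list where it did not stand apart: with no TMM to -0.08 for day 6 against day 4 and -0.09 for day 10 against day 4, and with TPM to -0.26 and -0.31. 0 called results reversed. Of 1419 checks on the other lists, 26 lost a call and 46 gained one, in 14 and 19 list comparisons; of 8220 checks on named genes, 730 moved by more than the counting interval and 0 called genes changed sign.

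Counts of changed genes depended on the pseudocount and the threshold by construction, since a larger added value shrinks the folds of low genes and a higher threshold takes fewer genes. For day 6 against day 4, 1033 rose and 863 fell; a pseudocount of 5 gave 472 and 451, a 4-fold threshold 151 and 86, and TPM 558 and 1629. For day 10 against day 6, 1058 and 910 became 562 and 452 with a pseudocount of 5 and 215 and 32 at 4-fold. For day 10 against day 4, 2190 and 2024 became 1324 and 1319 with a pseudocount of 5 and 603 and 396 at 4-fold, and the risers were 1383 with TPM.

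The time courses moved in the same way. With a pseudocount of 5, 89 genes rose at both steps, 359 rose to day 6 only, 448 rose after day 6 only, 24 rose then fell, 25 fell then rose, 373 fell to day 6 only, 375 fell after day 6 only and 53 fell at both. With a pseudocount of 0.1, 400 rose at both, 131 rose then fell, 179 fell then rose and 269 fell at both. With TPM, 382 rose to day 6 only, 1320 fell to day 6 only and 219 fell at both. TPM carries no TMM factor, and the median of all genes was -0.30 on the log2 scale for day 6 against day 4 under it and -0.14 for CPM with no TMM; any further cause was not tested. Depth limits genes near 1 CPM, where 1 fragment is worth 0.0918 CPM on day 4.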

Other observations

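The genes of this paragraph were chosen after their values were seen. RLN1, which codes for the hormone relaxin, fell 4.64-fold [4.31 to 4.99] from day 4 to day 6 and then rose 49.1-fold [46 to 52.5], to 3696 CPM. A search for genes at least 3-fold lower on day 6 than on day 4, at least 20-fold higher on day 10 than on day 6 and at 100 CPM or more on day 10 found 6, RLN1 and 5 genes without a symbol. LOC100341333 and LOC108175413, which lie between INSL4 and RLN1 in the mOryCun1.1 assembly, reached 7859 and 1122 CPM on day 10. LOC100346250, LOC100346509 and LOC100347029 reached 1131, 1032 and 879 CPM; their place is not given here. Reads shared between similar genes would give such parallel courses, and so would a common regulation; this was not tested. Among other genes without a symbol, LOC100342069 lies near IFIT3 and IFIT2 in that assembly and went from 4.86 to 197.6 to 69.8 CPM over days 4, 6 and 10, and LOC100353821, near CYP2A11, went from 11 to 7 to 4448 fragments.

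Of 9 simple epithelial and goblet markers 4 rose and 1 fell from day 4 to day 10 (percentile 97.9, a call lost with no minimum on CPM at 84.45, with a pseudocount of 0.1 at 94.83 and with TPM at 95.9): KRT7 rose 6.38-fold [5.54 to 7.38] and AGR2, which folds mucins, had 0 fragments on day 4 and 196 on day 10. Among ion transport genes 10 of 25 rose and 3 fell (percentile 99.7), with the carbonic anhydrases CA2 and CA12 at 21.3-fold and 10.3-fold. Of 8 epidermal keratins 3 rose and 2 fell (percentile 22.4), and KRT78 and KRT10 rose 20.3-fold [17.5 to 23.6] and 6.25-fold [5.45 to 7.19]. The WNT antagonist DKK1 was at 8.9 CPM on day 4, 2 fragments on day 6 and 16.5 CPM on day 10. Unfolded protein response genes fell in 10 of 27 cases with 1 up (percentile 1.32). The housekeeping, chromatin regulator and vascular endothelium lists stood apart in none of the 3 comparisons.

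In the paragraphs below, the tests of the day 6 library, of culture or handling, of THBS1 against the collagens, and of coding length at each single step were chosen only after the result was seen. The rise of interferon response genes at day 6 was not confined to that library. The list's median was 2.364 on day 10 against day 4, which argues against a deviation of the day 6 library alone. A deviation of the day 4 library alone stays open. Both rises are measured from that library, and the list did not stand apart from day 6 to day 10 (median -0.166, percentile 16.78). Immune cells in the culture stay open: 2 of the 5 leukocyte genes PTPRC, TYROBP, FCER1G, LAPTM5 and CORO1A lay under 1 CPM on day 6, both at 0, and none of the 5 rose. Against that, CD68, a macrophage and lysosome gene of the immune list, rose from 61 to 302 to 722 fragments, 3 of 6 measured immune genes rose from day 4 to day 10, LAPTM5 and CORO1A were already at 117.8 and 38.1 CPM on day 4 and a small number of cells could act through secreted interferon. A culture or handling difference cannot be told apart from the stage with 1 library per stage. The stage of differentiation itself stays open as a biological explanation, and was not tested.

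RNA left from the mouse feeder cells could account for part of the fall of fibroblast markers. The counts were made on the rabbit build OryCun2.0, so mouse RNA could enter them only through reads assigned to rabbit coding sequences. How many mouse reads were so assigned was not measured. The median CPM of COL1A1, COL1A2, COL3A1 and SPARC on day 4 was 1.4 times that of THBS1, as was predicted for feeder fibroblasts. SPARC alone, at 125.9 CPM, lay below THBS1 at 413.7 CPM. Expression of these genes by the epithelial cells could give that ratio too, so it cannot tell the source of the RNA. The ratio was taken on day 4 alone and does not bear on the fall. COL1A1 stood at 542 CPM in a culture of epithelial cells from which the feeders had been taken off with EDTA. Of the 25 measured markers 7 are also in another list, and how many the epithelial cells themselves express was not measured. A single loss of feeder RNA would lower its transcripts by a common factor, and THBS1 fell by 4.13 more on the log2 scale than the largest fall among those 4 genes, which argues against feeder cells of unchanged makeup as the whole cause for THBS1. The other markers did not share a factor either. From day 4 to day 10 the log2 difference was -1.03 for COL1A1 and -2.86 for COL6A2, while THY1 and TIMP1 rose. A single common factor therefore does not describe the list. A lower expression in the epithelial cells with differentiation stays open beside a loss of feeder RNA as part of the cause.

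From day 4 to day 10 all 33 ribosome biogenesis genes fell and the ribosomal protein list stood above random lists with 16 of 65 up, which a bias by coding length between the libraries could produce, since ribosomal proteins have short coding sequences (median 471 against 1312 bases over all genes). Against random lists matched on coding length and expression, the percentile of ribosome biogenesis genes was 0 in the length-matched test and that of ribosomal protein genes 99.04, which argues against coding length bias as the whole cause of either. Coding length had little trend in that comparison (Spearman rho -0.032); from day 4 to day 6, where it was -0.127, the percentiles were 0 and 99.86, and from day 6 to day 10 they were 0 and 89.4, so the small shift of ribosomal protein genes at the second step stays open to it. The matched lists for ribosomal proteins had a median of 0.60 against the 0.86 seen. Their draws could include the ribosomal protein genes themselves, so this median does not tell how other short abundant genes moved. The percentiles of that list are for the same reason partly a comparison with itself. Batch and handling were not separable from stage. A fall of ribosome production in cells that divide less is a hypothesis from the fall of MYC and S phase genes in the same libraries. By day 6, 23 of 33 ribosome biogenesis genes had fallen. Of the S phase genes 4 of 34 had, and of the G2 and M phase genes 1 of 41, so the falls were not in step. The hypothesis was not tested, and replicate cultures with a direct measure of ribosome production would test it.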
